A study of Tachycineta bicolor with 62 samples.

How the data were processed

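Brain tissue of 20 adult female tree swallows (Tachycineta bicolor) living in the wild was studied. Per the labels, competition among the experimental birds was raised by taking nest boxes away for a limited time, and control birds were left undisturbed and sampled on matching dates. Day 0 was the peak of competition, with 5 control and 6 experimental birds, and Day 2 came 2 days later, with 5 control and 4 experimental birds. Per the labels' protocols, brains were frozen in the field and dissected into regions, and RNA of hypothalamus and ventromedial telencephalon was sequenced from stranded mRNA libraries. DNA of the hypothalamus was sheared, methylated fragments were captured with a methyl-binding domain protein (MethylCap-seq), and the captured DNA was sequenced. The labels name 62 samples, of which 60 were used, namely 20 libraries each of hypothalamus RNA, telencephalon RNA and hypothalamus methylation. The negative and the positive capture control were not analysed here. A further 14 columns of RNA counts belong to no labelled sample and were used in no step. The abbreviation in the names of the telencephalon columns is not explained in the labels, and those columns were taken as telencephalon because each bird had 1 hypothalamus column and 1 other.

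The deposited RNA values were counts, whole numbers of reads per transcript with no normalization. The deposited methylation values were a signal, the mean coverage per base of each bin of 250 bp. All 50797200 values were whole multiples of 1 step per library, with deviations of at most 1.3e-08 steps, so the authors' values were coverage multiplied by 1 factor per library. That step was used to recover each library's coverage before scaling, summed over all positions. This sum is called covered bases below and measures depth, not the part of the genome covered. Per the submitters' processing notes, the tools included bcl2fastq 2.20.0, Trimmomatic 0.36, Bowtie2 2.3.4.3, BWA 0.7.17-r1188, SAMtools 1.9, Picard, DESeq2 and R 3.6.0. The role of each tool, the reference sequences, the genome build behind the contigs, the counter, its use of strand and the choice of the scale factors are not given in the sources used here. Factors that differ between groups shift the coverage of all bins together, and transcripts with similar sequences can share counts. The count table names transcripts by numbered IDs and the files do not pair the IDs with gene names. None of the 13412 IDs matched a member of the 28 gene lists fixed in advance, so the gene list tests gave no value.

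The names of the methylation columns give the control birds' periods the other way round from the sample titles, for 10 of 10 control birds and 0 of 10 experimental birds. The titles were followed, and the tests of transcripts and bins by day, the correlations of fold changes, and the top 1% share and mean of coverage by day were repeated with the control days exchanged. The mean of the differences on both days, each day against its own controls, does not depend on that choice and was added after the data had been seen, as were the methylation comparisons of treatment by day and of the control days.

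RNA counts were analysed with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr, libraries were scaled by TMM, and the 4 groups of a tissue were fitted together by the quasi-likelihood method with robust moderation. Transcripts at a Benjamini-Hochberg adjusted p under 0.05 were called. Within a tissue, p-values rest on the spread between separate birds. Tissues were compared in 1 fit of all 40 RNA libraries with a mean for each group, and the tissue difference was the mean over the 4 pairs of groups. This fit treated the 2 libraries of a bird as independent, and bird as a block was an alternative. Both tissues came from the same animals, since the titles give a bird number that recurs in both tissues and in the DNA, so the numbers pair the samples. In the check of this pairing, the deviations of the libraries from their group means correlated at r over 0.1 between the tissues in 14 of 20 birds, with a median r of 0.17. The lowest r was -0.195, and only 6 of 20 birds correlated best with their own other tissue. By itself this check does not settle the pairing. Levels are given as CPM, counts per 1e+06 counts of the TMM-scaled library, and log CPM for components used a prior count of 2.

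Methylation bins were tested with limma 3.58.1 on log2 of normalized coverage plus a pseudocount of 1, with trended and robust moderation and all 4 groups in 1 fit. A fold change on this scale understates the change of bins with low coverage. Bins were tested if above 0 in at least 4 libraries and at or above the median of such bins in mean coverage, which kept 1195069 of 2539860 bins. The share of coverage in the top 1% of bins was compared by two-sided exact permutation tests within days. Correlations over birds were tested with 1e+05 shuffles. The correlation of fold changes on the 2 days was set against shuffles of the treatment among the Day 2 birds.

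Methods were tested on simulated data. RNA counts were drawn independently for each transcript from the real means, library sizes and dispersions. Methylation values were drawn independently for each bin from its real mean and residual SD on the log2 scale of the test. These draws had no lower limit, and increases and decreases were pooled. At the median tested coverage of 3.87, an 8-fold decrease on this scale would need negative coverage. The methylation recovery below therefore does not hold for large decreases in bins of low coverage. No difference shared by whole libraries was simulated, so the recovery and the false calls below hold only for data without one. With 200 changed transcripts, edgeR recovered 76.1% of 2-fold changes in telencephalon on Day 0 and 73.1% on Day 2, with 38.8% and 35.8% of 1.5-fold changes. In hypothalamus it recovered 70.1% and 62.7% of 2-fold changes on Day 0 and Day 2, and 34.3% and 25.4% of 1.5-fold changes. For the tissue difference, 68.7% of 1.5-fold changes were recovered. With 3000 changed bins, limma recovered 2.6% of 2-fold, 47.9% of 4-fold and 91.5% of 8-fold changes on Day 0, and 0.8%, 34.8% and 85.8% on Day 2, with 60 and 65 false calls.

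Alternatives chosen before the data were examined were size factors of the DESeq2 type, DESeq2 1.42.0, no filter, a fit of the compared groups alone, 1 surrogate variable from sva 3.50.0, bird as a block, pseudocounts 5 times larger or smaller, equal upper quartiles, other top shares of bins, and leaving out each bird in turn. Added after the data had been seen were the exchanged control days, methylation moderation without the robust option, and 2 library covariates for methylation. The covariates were the share of coverage in the top 5% of bins and log2 of covered bases. Under the rule fixed in advance, transcripts without a gene name were named only where a comparison had no other calls, as in all RNA comparisons here. At most 2 transcripts per direction are named, those with the smallest p at a mean of 1 CPM or more, and at most 5 bins per direction with the smallest p.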

Results

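Gene expression was measured by RNA sequencing in the hypothalamus and the ventromedial telencephalon of 20 free-living female tree swallows, and DNA methylation by MethylCap-seq in the hypothalamus of the same birds. Experimental birds had met raised competition after nest boxes were temporarily taken away, and controls were undisturbed birds of matching dates. Birds were sampled at peak competition (Day 0, 5 controls and 6 experimental birds) or 2 days later (Day 2, 5 controls and 4 experimental birds). Total counts per library were 6446505 to 9888794 in hypothalamus and 5802713 to 9082912 in telencephalon. The table held 13412 transcripts, of which 43 had no count in any of the 40 libraries. Each of the 82 pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 8.73 to 45.5. The methylation table covered 635 Mb in 2539860 bins of 250 bp on 7859 contigs, at a mean coverage of 2.96 to 6.25 reads per base before the authors' scaling. The genome build of the contigs is not given in the sources used here, and no gene annotation was used with them.

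The hypothalamus and the telencephalon differed in the level of 6321 of 11995 tested transcripts (52.7%). In hypothalamus 3013 of these were higher and 3308 lower, and 142 were higher and 293 lower by at least 2-fold. The transcript tree_swallow006029 averaged 156 ± 72.6 CPM in hypothalamus and 12.3 ± 5.34 CPM in telencephalon (SD, n = 20 birds), a 12.7-fold difference. Likewise, tree_swallow005444 averaged 110 ± 52.1 against 10.9 ± 5.36 CPM, a 9.99-fold difference, and both were higher in hypothalamus in 20 of 20 birds. In the other direction, tree_swallow009324 averaged 0.792 ± 0.558 CPM in hypothalamus and 13.1 ± 7.9 CPM in telencephalon, and tree_swallow005162 averaged 61.7 ± 9.05 against 111 ± 12.5 CPM. Neither was higher in hypothalamus in any bird (0 of 20). In edgeR's quasi-likelihood test over all 40 libraries, the log2 fold changes of the higher pair were 3.66 (SE 0.21) and 3.32 (SE 0.19), both at an adjusted p of 1.54e-15. Those of the lower pair were -4.02 (SE 0.29, edgeR adjusted p 5.09e-13) and -0.85 (SE 0.06, edgeR adjusted p 2.16e-12).

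**Figure D1:**
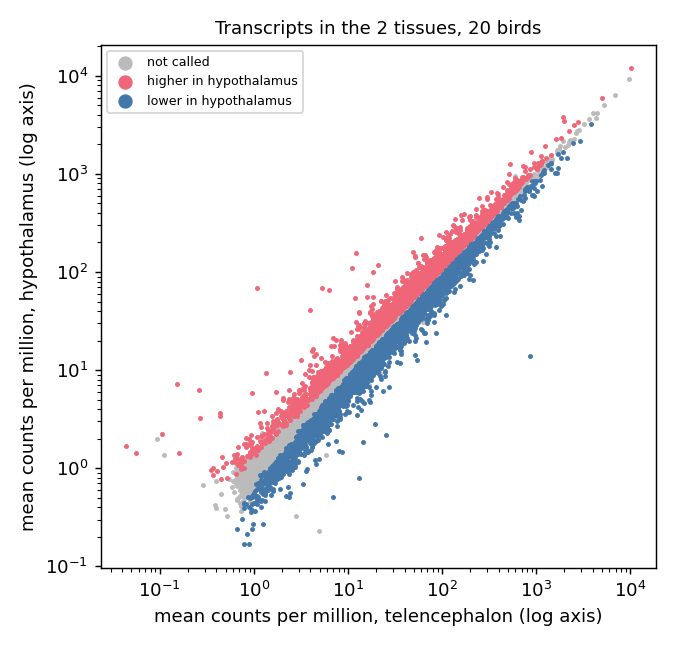
Mean CPM of each tested transcript in telencephalon (x) and hypothalamus (y) over 20 birds, both on log axes. Points in color are the 3013 transcripts higher and the 3308 lower in hypothalamus at an adjusted p under 0.05 in edgeR, and gray points are the remaining tested transcripts.

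The first treatment question was how the brain of females at the peak of competition differed from that of undisturbed females. On Day 0, 1 transcript was called in each tissue, and it was the same one, tree_swallow007899, lower in experimental birds. In telencephalon it averaged 14.6 ± 3.75 CPM (SD, n = 6) in experimental birds and 41.9 ± 14.1 CPM (n = 5) in controls. In hypothalamus it averaged 10.1 ± 1.85 CPM (n = 6) against 27.7 ± 7.99 CPM (n = 5). Every experimental bird lay below every control bird in both tissues. The log2 fold change was -1.51 in telencephalon (SE 0.22, 95% interval -1.98 to -1.05, edgeR adjusted p 0.0132) and -1.45 in hypothalamus (SE 0.22, 95% interval -1.91 to -0.99, edgeR adjusted p 0.0237). Among 11788 and 11785 tested transcripts, 797 in telencephalon and 366 in hypothalamus had an unadjusted p under 0.05. DESeq2 called 4 transcripts in telencephalon, all lower, and 7 in hypothalamus, 4 higher and 3 lower, and gave tree_swallow007899 an adjusted p of 3.1e-07 and 6.41e-06. The 95% interval of the fold change lay within 2-fold of no change for 85.3% of transcripts in telencephalon and 82.4% in hypothalamus. The edgeR call was lost when the 2 Day 0 groups were fitted alone (adjusted p 0.101 in telencephalon, 0.125 in hypothalamus), with 1 surrogate variable in telencephalon (0.108), and in 5 of 11 (telencephalon) and 9 of 11 (hypothalamus) fits without 1 bird, with adjusted p from 3.1e-07 and 6.41e-06 (DESeq2) to 1 over all settings. With the control days as the methylation column names give them, the Day 0 log2 fold change was -0.13 (SE 0.23) in telencephalon and -0.52 (SE 0.22) in hypothalamus, and the Day 2 value was -1.09 (SE 0.25) and -0.74 (SE 0.24), none called by edgeR.

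**Figure D2:**
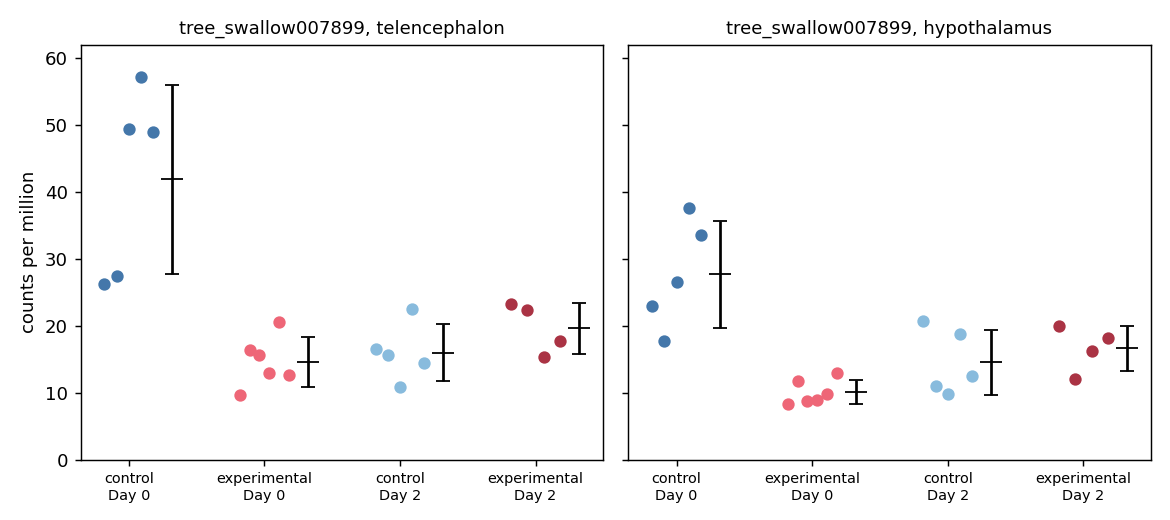
Level in CPM of tree_swallow007899 in each bird by group, in telencephalon and hypothalamus, with the mean and SD of each group as a bar beside its points. Control birds of Day 0 averaged 41.9 and 27.7 CPM, and the means of the other groups lay between 10.1 and 19.6 CPM.

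The second question was what differed 2 days after the peak of competition. On Day 2 no transcript was called in telencephalon (0 of 11788 in edgeR) or in hypothalamus (0 of 11785), with smallest adjusted p of 0.279 and 0.104. At an unadjusted p under 0.05 there were 577 (4.89%) and 551 (4.68%) transcripts, about as many as independent transcripts without a difference would give. Transcripts are not independent, so these shares do not show that differences were absent. DESeq2 called 10 (5 higher, 5 lower) and 4 (2 higher, 2 lower). The level of tree_swallow007899 was 19.6 ± 3.74 CPM in experimental birds (n = 4) and 16 ± 4.25 CPM in controls (n = 5) in telencephalon, and 16.6 ± 3.41 against 14.6 ± 4.89 CPM in hypothalamus. Its Day 2 log2 fold changes were 0.29 (SE 0.25) and 0.20 (SE 0.24), both at an edgeR adjusted p of 0.995. The 95% interval lay within 2-fold of no change for 85% of transcripts in telencephalon and 79.8% in hypothalamus. Without control Day 2 bird 19, edgeR called 6 transcripts in telencephalon. In hypothalamus, edgeR called 1 transcript, higher, with 1 surrogate variable, and 1, lower, with the control days exchanged.

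Whether the response changed between the days was tested directly. For the difference between the 2 responses, edgeR called 0 transcripts in either tissue. At an unadjusted p under 0.05 there were 586 in telencephalon (4.97%) and 247 in hypothalamus (2.1%), no more than chance alone gives. DESeq2 called 3 in telencephalon, all with a higher response on Day 2, and 6 in hypothalamus, 4 higher and 2 lower. The response of tree_swallow007899 differed by 1.81 on the log2 scale in telencephalon (edgeR adjusted p 0.24, DESeq2 0.00149) and by 1.65 in hypothalamus (edgeR adjusted p 0.298, DESeq2 0.00694). Over both days together, edgeR called 0 transcripts in either tissue, with 702 and 784 at an unadjusted p under 0.05, and DESeq2 called 4, all lower, and 5, 2 higher and 3 lower. Across transcripts, which are not independent replicates, the fold changes of Day 0 and Day 2 correlated at r = 0.184 in telencephalon and 0.16 in hypothalamus. Other assignments of treatment among the Day 2 birds gave values of -0.427 to 0.427 and -0.478 to 0.477, so neither correlation exceeded what relabelled birds gave (permutation p 0.43 and 0.67). Without 1 bird the telencephalon value was 0.014 (experimental Day 2 bird 37) to 0.267 (experimental Day 2 bird 12), and the hypothalamus value 0.003 (control Day 2 bird 24) to 0.316 (control Day 2 bird 19). With the control days exchanged, the hypothalamus value was -0.176, and without control Day 2 bird 19 edgeR called 3 transcripts for the difference between the responses in telencephalon and 1 over both days.

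Control birds were compared between the days as the background against which the treatment was read. For controls, edgeR called 0 transcripts in telencephalon, where 891 had an unadjusted p under 0.05 and DESeq2 called 4 (1 higher, 3 lower). In hypothalamus edgeR called 0, with 432 at an unadjusted p under 0.05, and DESeq2 called 0. The transcript tree_swallow007899 was the one nearest to the threshold in telencephalon, with a log2 difference of -1.39 from Day 0 to Day 2 (SE 0.24, edgeR adjusted p 0.0977, DESeq2 6.13e-05), and its hypothalamus value was -0.93 (SE 0.23, edgeR adjusted p 0.892). Without control Day 2 bird 19, edgeR called 2 transcripts in telencephalon, and without control Day 0 bird 6 or bird 7 it called 1.

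The response to treatment was also compared between the tissues of the same birds, in a fit that left out the pairing by bird. No transcript was called as responding differently in hypothalamus and telencephalon on Day 0 (0 of 11995 in edgeR, 83 at an unadjusted p under 0.05, 0 in DESeq2) or on Day 2 (0 in edgeR, 109 at an unadjusted p under 0.05, 0 in DESeq2). The Day 0 response of tree_swallow007899 differed between the tissues by 0.06 on the log2 scale (SE 0.32, edgeR adjusted p 1). The size of difference this comparison could detect was not simulated, so the absence of calls does not show equal responses.

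The largest differences among hypothalamus libraries did not follow the study groups. The first principal component of hypothalamus held 43.2% of the variance and that of telencephalon 20.9%. Of the variance along these components, 84.2% in hypothalamus and 78.3% in telencephalon lay within the 4 groups. Treatment was not associated with the first component within days, at an exact permutation p of 0.318 in hypothalamus and 0.263 in telencephalon.

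**Figure D3:**
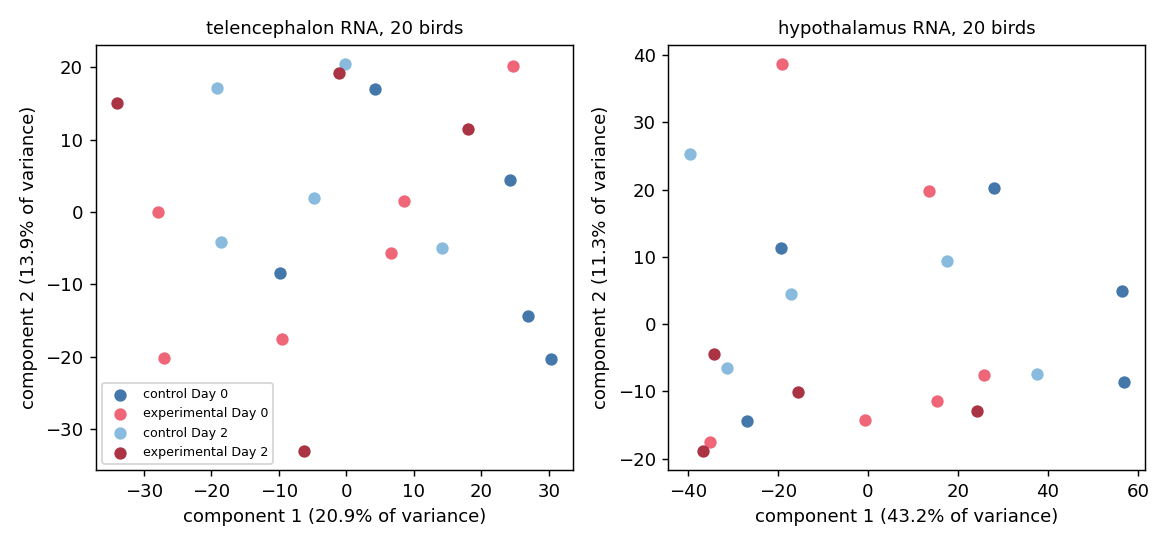
Scores of the 20 birds on the first and the second principal component of log CPM in telencephalon and in hypothalamus, colored by group. Component 1 held 20.9% and 43.2% of the variance, and the birds of each group were spread along it.

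In the hypothalamus methylome, the number of bins called on a single day was low but changed with the settings. On Day 0, 1 of 1195069 tested bins was called, on contig VKGD01001421.1 at 36251 to 36500. Its normalized coverage was 2.38 ± 1.88 in experimental birds (SD, n = 6) and 21.6 ± 16.6 in controls (n = 5), a log2 difference of -2.68 (SE 0.44, limma adjusted p 0.0137). At an unadjusted p under 0.05 there were 118419 bins. The bin was called in 5 of 11 fits without 1 bird and had limma adjusted p from 0.000108 to 0.65 over all settings, among them 0.117 with equal upper quartiles and 0.472 with a smaller pseudocount. It had a log2 difference of -1.25 with the control days exchanged. The number of Day 0 calls was 0 to 14 without 1 bird, 46 with a larger and 0 with a smaller pseudocount, 192 without the filter, 36 with the 2 groups alone and 0 with equal upper quartiles. The 95% interval lay within 2-fold of no change for only 15% of tested bins on Day 0 and 8.41% on Day 2. The low number of calls therefore does not show that most bins were without 2-fold differences.

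On Day 2, 7 bins were called, 6 lower and 1 higher in experimental birds. Of the lower bins, 3 were neighbours that covered 29751 to 30500 of contig VKGD01001718.1. The first of them, 29751 to 30000, had a coverage of 42.5 ± 22 in experimental birds (SD, n = 4) and 136 ± 56.3 in controls (n = 5), a log2 difference of -1.72 (SE 0.3). The others differed by -1.68 (SE 0.29) and -1.75 (SE 0.32). Single lower bins lay on VKGD01000314.1 at 196751 to 197000 (log2 difference -2.83, SE 0.5) and on VKGD01001401.1 at 64501 to 64750 (log2 difference -2.57, SE 0.46), and the remaining one differed by -2.73. The higher bin, on VKGD01001648.1 at 65751 to 66000, had a coverage of 75.6 ± 27.2 against 18 ± 6.03 (log2 difference 2.00, SE 0.36). The limma adjusted p was 0.0392 for each of the 7 bins, and 73819 bins had an unadjusted p under 0.05. With the control days exchanged, the 3 neighbouring bins were called (limma adjusted p 0.0166, 0.0117 and 0.0117, range over all settings and the 3 bins 0.00223 to 0.503), whereas the higher bin had a log2 difference of 0.09, and 1506 bins in all were called. Without 1 bird, the 3 neighbouring bins were called in 5, 5 and 2 of 9 fits, the bin on VKGD01001401.1 in 3 of 9, and the other 3 bins in 2 of 9 each. With equal upper quartiles none of the 7 was called, at adjusted p from 0.0562 to 0.0769 in limma.

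Over both days together, 808 bins were called, and 802 of them (99.3%) had less coverage in experimental birds. They lay in 686 separate regions on 325 contigs. At an unadjusted p under 0.05 there were 141689 bins, 83.8% of them lower, but with equal upper quartiles there were 114146, of which 42.3% were lower, so the general direction depended on the scaling. The bin with the smallest p, on VKGD01000141.1 at 309751 to 310000, had a coverage of 10.7 ± 5.53 in experimental birds (SD, n = 6) and 33.4 ± 8.46 in controls (n = 5) on Day 0. On Day 2 it had 7.75 ± 3.33 (n = 4) against 30.8 ± 13.3 (n = 5). Its log2 difference was -1.76 (SE 0.27, limma adjusted p 0.00223). It was called in 20 of 20 fits without 1 bird and in 6 of 7 other settings, the exception being a smaller pseudocount (limma adjusted p 0.0745, range 5.24e-05 to 0.0745). Of the 6 higher bins, the one with the smallest p lay on VKGD01000289.1 at 285501 to 285750, with coverages of 7.58 ± 1.88 against 2.86 ± 0.688 on Day 0 and 6.4 ± 1.6 against 1.01 ± 0.996 on Day 2 (log2 difference 1.57, SE 0.32, limma adjusted p 0.0325), and it was called in 13 of 20 fits without 1 bird and 2 of 7 other settings. The number of calls depended on the settings, at 2 with equal upper quartiles, 3 with the top 5% share and 82 with covered bases as a covariate, 44 without robust moderation, and 0 and 3350 with a smaller and a larger pseudocount. The median log2 difference of all tested bins moved from -0.107 to 0.071 with equal upper quartiles. It also depended on single birds, from 5 calls without control Day 2 bird 24 or experimental Day 0 bird 15 to 7513 without control Day 2 bird 38. For the difference between the responses on the 2 days, limma called 0 bins, with 46424 at an unadjusted p under 0.05. The 95% interval lay within 2-fold of no difference for 1.11% of bins in that comparison, against 57.7% over both days. The absence of calls for the difference between the days therefore does not show equal responses.

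Methylation was also compared between the control birds of the 2 days, after the data had been seen. Of 100 splits of these birds, 16 gave at least as many calls as the real one, itself included, so chance cannot be excluded. From Day 0 to Day 2, 5 bins were called, all lower on Day 2, and 3 of them were neighbours at 122251 to 123000 of contig VKGD01000635.1. The middle one had a coverage of 190 ± 43 on Day 0 and 55.6 ± 16 on Day 2 (SD, n = 5 each), a log2 difference of -1.77 (SE 0.28, limma adjusted p 0.00483). Another was the bin on VKGD01001648.1 that was higher in experimental birds on Day 2, with 76.6 ± 40 in controls on Day 0 and 18 ± 6.03 on Day 2 (log2 difference -1.91, limma adjusted p 0.0382). At an unadjusted p under 0.05 there were 105635 bins, and the median log2 difference of all tested bins was -0.172, against -0.157 for treatment on Day 0. The number of calls was 1 with equal upper quartiles or covered bases as a covariate, 0 and 90 with a smaller and a larger pseudocount, 836 without the filter, and 1 (without control Day 0 bird 11) to 86 (without control Day 2 bird 23) without 1 bird. With the control days exchanged the same bins count as higher on Day 2.

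**Figure D4:**
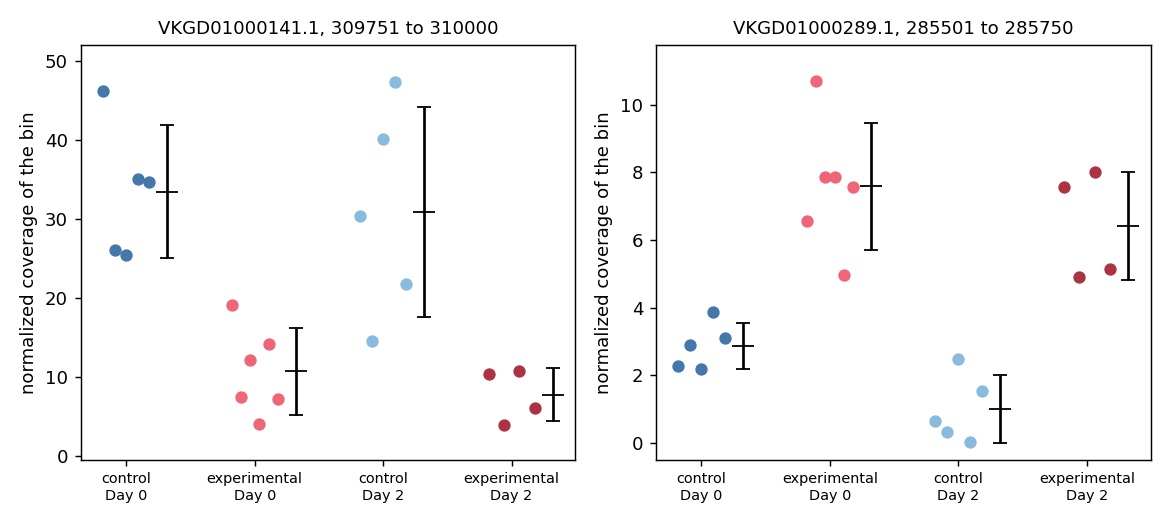
Normalized coverage of 2 methylation bins in each bird by group, with the mean and SD of each group as a bar beside its points. The left bin, 309751 to 310000 on VKGD01000141.1, was lower in experimental birds, and the right bin, 285501 to 285750 on VKGD01000289.1, was higher.

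As a stand-in for the enrichment of the capture, the share of each library's coverage in the top 1% of bins was compared. This share was not checked against sequence content or the capture controls, so it need not measure enrichment. On Day 0 the share was 30.7 ± 1.56% in experimental birds (SD, n = 6) and 32.5 ± 3.29% in controls (n = 5), a difference of -1.79 percentage points (two-sided exact permutation p 0.294). On Day 2 it was 32.8 ± 1.89% (n = 4) against 31.2 ± 0.738% (n = 5), a difference of 1.54 points (exact permutation p 0.119). Mean normalized coverage of all bins was 4.93 ± 0.418 in experimental birds and 5.85 ± 0.42 in controls on Day 0 (exact permutation p 0.0108), and 4.74 ± 0.342 against 5.17 ± 0.709 on Day 2 (exact permutation p 0.317). With the control days exchanged these differences were -0.234 on Day 0 (exact permutation p 0.517) and -1.11 on Day 2 (exact permutation p 0.0159). Over both days together, the comparison that gave the 808 bins, it differed by -0.672 (exact permutation p 0.00996). The mean coverage was compared after the data had been seen, and of 18 exact tests of library values the 6 of the top shares by day were chosen in advance, 4 of them as alternatives. Without experimental Day 2 bird 12 the Day 2 share differed by 2.4 points (exact permutation p 0.0179). Without control Day 0 bird 8 the Day 0 share differed by -0.424 points (exact permutation p 0.69). For the top 5% of bins the differences were -4.59 points on Day 0 and -0.754 on Day 2 (exact permutation p 0.0433 and 0.698), the latter opposite in sign to that of the top 1%. For the top 0.1% they were -1.2 and 1.05 points (exact permutation p 0.11 and 0.0397).

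**Figure D5:**
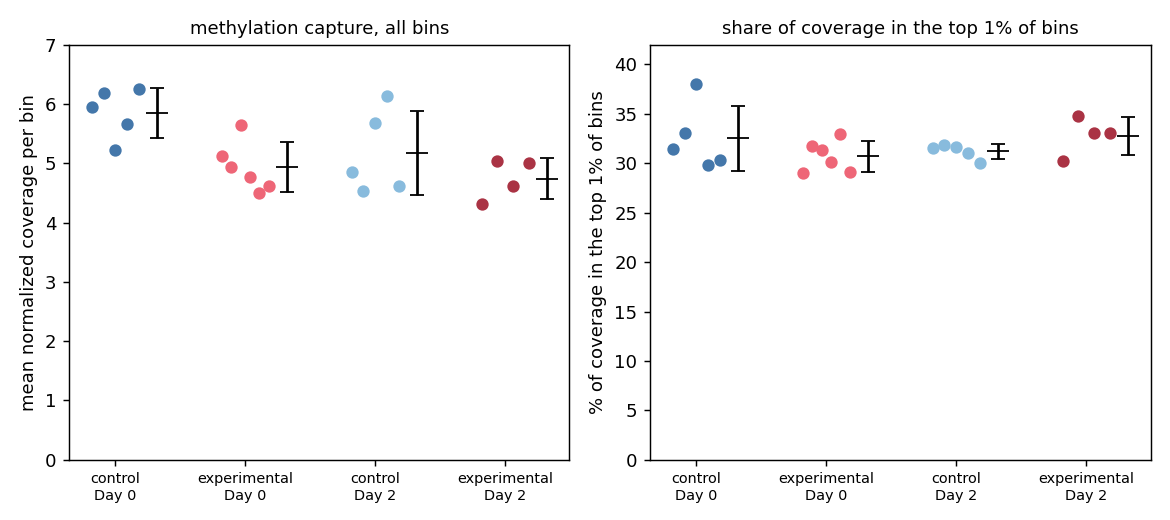
Mean normalized coverage per bin (left) and percent of coverage in the top 1% of bins (right) in each methylation library by group, with the mean and SD of each group as a bar beside its points. Mean coverage was 5.85 in controls and 4.93 in experimental birds on Day 0.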

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

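Tests chosen only after their results were seen were those of study group for the component, of capture enrichment and depth for methylation, of all 3 counts of bins still called, and of a single bird and exchanged days for tree_swallow007899. The methylation comparison over both days and the relations of the component with library values were also added after the data had been seen.

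The hypothalamus libraries spread along 1 component that held 43.2% of the variance. Depth as its cause was argued against, since thinning every library to the lowest total left 0.992 of that share (42.8%), and study group as its cause was argued against by the 84.2% of its variance that lay within groups. Telencephalon tissue in the dissections was tested on 4261 transcripts that follow the component, and 98.1% of them spanned more than the whole tissue difference (80.2%) or went against it (17.9%), beyond the 50% set in advance. Of 4256 transcripts compared at the component's end nearer to telencephalon, 51.3% passed the telencephalon mean, which mixing alone cannot do. The result is weakened because 80.3% moved toward telencephalon at that end. Over all shared transcripts, the loadings on the component also correlated with the tissue difference, at an absolute r of 0.52. Mixing in every dissection would moreover shrink the tissue difference that the 50% bound uses. The score rose with the number of transcripts at 0 (r = 0.853, rho = 0.801, permutation p 1e-05 for r, the smallest these shuffles can give, 3e-05 adjusted over 3 relations, and r = 0.774 without the 2 farthest birds), so RNA quality or other neighbouring tissue may contribute, which was not tested.

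Over both days, 802 of 808 called methylation bins were lower in experimental birds. Rescaling to equal upper quartiles, the share of coverage in the top 5% of bins as a covariate, and covered bases as a covariate left the median difference of these bins at -4.12, -3.77 and -4.19 times its median SE, against -4.58 uncorrected, which meets the bound of 2 SE set in advance for the scaling but decides nothing, because bins picked for their difference keep a large median under any small correction. The median log2 difference was -1.334 uncorrected and -1.136, -1.198 and -1.238 corrected, with median SE of 0.292 uncorrected and 0.276, 0.318 and 0.295. Only 2, 3 and 71 of the 808 bins were still called, while the bins at an unadjusted p under 0.05 fell from 141689 to 114146, 92159 and 129501, and what ended the calls was not tested further, so the authors' scaling, capture enrichment and library depth may each account for the number of calls. None of the 3 is excluded as a cause of the difference, the equal upper quartiles turned the median of all tested bins from -0.107 to 0.071, and a lower level of methylation in experimental birds stays open beside these.

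The transcript tree_swallow007899 was lower in experimental birds on Day 0 in both tissues. A single outlying bird was argued against, since every fit without 1 bird kept at least 0.91 of the log2 fold change. A level set by the individual bird in both tissues met its prediction, as the birds' deviations from their group means correlated between the tissues (r = 0.597, rho = 0.565, permutation p 0.0056 for r, 0.0084 adjusted over 3 relations, and r = 0.561 without the 2 farthest birds). The 2 tissues may therefore not be independent evidence for the treatment. Exchanged control days cannot be told apart from the titles' days, because the 2 label sources disagree and the exchange gave a Day 2 difference of -4.36 times its SE in telencephalon and -3.08 in hypothalamus, with -0.565 and -2.36 left on Day 0, the last beyond the 1 SE the exchange would need, and high levels in the control birds of 1 day stay open too.

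Of 60 groups of values compared for a bird far from the rest, 3 held one, and about 1 in 20 groups holds one by chance. In telencephalon on Day 0, experimental bird 5 had 28.9 CPM of tree_swallow006029 (others 7.07 to 14.7), and experimental bird 16 had 21.4 CPM of tree_swallow009324 (others 4.74 to 10.7). In hypothalamus on Day 2, experimental bird 50 had 79.7 CPM of tree_swallow005162 (others 51 to 54.6). These birds were kept in every comparison except where each bird was left out in turn.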

How the results depend on the processing

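The exchanged control days, moderation without the robust option, the 2 covariates, the values over both days and the methylation values of treatment by day and of the control days were chosen after the data had been seen. The gene lists had no value, and the cause of the changes below was not tested except where given.

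DESeq2 called 4 transcripts in telencephalon and 7 in hypothalamus on Day 0, 10 and 4 on Day 2, 3 and 6 for treatment by day, 4 and 5 over both days, and 4 for the control days in telencephalon. With the compared groups alone, edgeR called 0 in either tissue on Day 0. With 1 surrogate variable it called 0 in telencephalon on Day 0 and 1 in hypothalamus on Day 2. With control days exchanged it called 0 in either tissue on Day 0 and 1 in hypothalamus on Day 2, and the hypothalamus correlation was -0.176. With bird as a block, 6737 transcripts differed between the tissues, 6147 of them called in both fits and all in the same direction, and the block left treatment by tissue at 0.

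Without 1 bird, edgeR called 0 to 2 transcripts on Day 0 in each tissue, with 2 without control bird 9 in telencephalon and control bird 7 in hypothalamus. In telencephalon tree_swallow007899 had an adjusted p of 0.0728 without control bird 8, 0.0724 without 11, and 0.0531, 0.0638 and 0.0672 without experimental birds 3, 15 and 18. In hypothalamus it had 0.0523, 0.0629, 0.141 and 0.2 without control birds 6, 8, 9 and 11, and 0.171, 0.0864, 0.176, 0.174 and 0.0981 without experimental birds 3, 4, 5, 15 and 16. Its log2 fold change stayed at -1.64 to -1.38 and -1.57 to -1.32. The telencephalon counts were 0 to 6 on Day 2, 0 to 3 for treatment by day, 0 to 2 for the control days and 0 to 1 over both days, each highest without control Day 2 bird 19.

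Methylation calls on Day 0, on Day 2 and over both days were 46, 6 and 3350 with a pseudocount 5 times larger, 0, 0 and 0 with one 5 times smaller, 192, 46 and 2165 without the filter, and 0, 0 and 2 with equal upper quartiles. They were 8, 0 and 44 without robust moderation, 1 (higher), 3 and 3 with the top 5% share as a covariate, and 2, 16 and 82 with covered bases. The groups alone gave 36 and 4 calls, and exchanged control days 4 and 1506. Treatment by day gave 2 with the larger pseudocount, 11 without the filter and 14 with exchanged days. The control days gave 90 and 0 with the larger and smaller pseudocount, 836 without the filter, 1 with equal upper quartiles, 11 with the groups alone and 1 with covered bases.

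Without 1 bird, methylation calls were 0 to 14 on Day 0, with 0 without control birds 6, 7 and 11 and experimental birds 3 and 15, 14 without control 8, and 8, 4 and 3 without experimental 5, 4 and 16. On Day 2 they were 0 to 14, with 0 without control birds 22 and 23 and experimental 50, 2 without control 24, 14 without control 38, and 11 and 12 without experimental 12 and 37. Over both days they were 5 to 7513. Without control birds 24, 7, 6, 23, 9, 11 and 22 they were 5, 15, 20, 50, 249, 404 and 531, and without experimental birds 15, 50, 18, 16 and 4 they were 5, 10, 41, 88 and 190. Without control 19 and 38 they were 2400 and 7513, and without experimental 12, 3, 37 and 5 they were 1634, 1979, 2288 and 3655. Treatment by day gave 0 to 1, with 1 without control 22, 23 or 24. The control days gave 1 to 86, with 25, 2, 86, 50 and 3 without Day 2 birds 19, 22, 23, 24 and 38, and 3, 2, 27, 21 and 1 without Day 0 birds 6, 7, 8, 9 and 11.

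The top share differed by -4.59 points on Day 0 and -0.754 on Day 2 for the top 5% of bins, and by 1.05 on Day 2 for the top 0.1%. Without 1 bird it was -2.44 to -0.424 points on Day 0 and 0.883 to 2.4 on Day 2, the highest without experimental bird 12 (exact permutation p 0.0179).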

Other observations

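Tests chosen only after their results were seen were those of bird identity, of transcripts with a gap between birds and of very high transcripts, and the splits of birds for telencephalon, for treatment by tissue, for the difference between days and the control days in methylation, and for hypothalamus RNA other than the Day 0 calls and the correlation. The methylation comparison over both days was itself added after the data had been seen.

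After the first 2 to 5 components of each tissue were removed, 20 of 20 birds correlated best with their own other tissue across 11656 transcripts. With none removed this held for 4 birds, and with 1 removed for 15. A gap of at least 2 log2 units between birds was found for 5 transcripts in each tissue, of which 3 were shared, and all 3 parted the same birds in both tissues, against 0 in 100 shuffles of the birds. Levels of tree_swallow024074 were 0 CPM in hypothalamus and 0.15 to 0.267 CPM in telencephalon in birds 3, 7, 16 and 50, and 6.51 to 41.7 and 12.2 to 50 CPM in the others. The same 4 birds had 0 CPM and 0 to 0.15 CPM of tree_swallow081322, against 1.09 to 11.7 and 1.97 to 15.1 CPM. Birds 6, 7, 9 and 16 had 78.7 to 197 CPM (hypothalamus) and 105 to 130 CPM (telencephalon) of tree_swallow000990, against 1.27 to 16 and 1.87 to 11 CPM. These 3 transcripts were chosen after their values were seen.

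In telencephalon, tree_swallow034143, also chosen after its values were seen, reached 7790 CPM in control Day 0 bird 11, 6720 CPM in control Day 2 bird 38 and 2010 CPM in control Day 0 bird 9. Control Day 2 bird 19 had 419 CPM and the next bird 71.6 CPM. The highest hypothalamus value was 60.3 CPM and the median of all 40 libraries 15.1 CPM. It was the only transcript to exceed both 1000 CPM and 20 times its median in a library.

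For the RNA comparisons, 100 splits of the birds, the real one included, were counted. In telencephalon on Day 0, 4 splits gave as many calls as the real one (real 1, highest other 4). In hypothalamus 3 did (real 1, highest other 2816). Both shares lie under 1 in 20, but without correction for the other comparisons and from only a part of the possible splits. Each rests on 1 call, both tissues came from the same birds, and the telencephalon splits were chosen after their result was seen. Chance is therefore not excluded for either tissue. For the tissues, with labels exchanged within birds so that every split parted all 20 pairs, only the real split (1 of 100) reached its count (real 6321, highest other 1933), and chance can be excluded. Where the real count was 0, all 100 splits reach it whatever the data, so the splits say nothing about chance. In these comparisons the highest other counts were 9 for telencephalon Day 2, 2 for treatment by day, 6 over both days and 7 for the control days, and 5, 1, 2605 and 4720 in hypothalamus. For treatment by tissue the highest other counts were 3042 on Day 0 and 0 on Day 2. Splits with 2605 to 4720 calls in hypothalamus or for treatment by tissue point to a structure of the samples, though what those splits share was not tested. For the correlations of fold changes, 43 splits reached the telencephalon value (real 0.184, farthest other 0.427) and 67 the hypothalamus value (real 0.16, farthest other -0.478), so chance cannot be excluded.

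For methylation, 28 of 100 splits gave as many calls as the real one on Day 0 (real 1, highest other 40) and 10 on Day 2 (real 7, highest other 410), so chance cannot be excluded. Over both days 2 of 100 splits did (real 808, highest other 2228), and 26 of the 99 other splits had any call. The 2 of 100 lie under 1 in 20, but without correction and for a comparison added after the data had been seen. The count was 5 to 7513 without 1 bird and 2 with equal upper quartiles. Chance is therefore not excluded, and the splits cannot part differences of bins from a shift of whole libraries. For the control days 16 of 100 splits gave as many calls as the real one (real 5, highest other 6411), so chance cannot be excluded. For the difference between the days the real count was 0, which all 100 splits reach whatever the data, so this says nothing about chance (highest other 3540). Counts many times the real one point to a structure of the samples, though what those splits share was not tested.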
